A study of Solanum tuberosum with 8 samples.

How the data were processed

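RNA of meristems cut from tubers of the potato cultivar Russet Burbank was sequenced in 8 samples, 4 dormant and 4 nondormant, from 4 harvests. Per the labels' protocols, meristems were excised with a small curette and frozen, total RNA was extracted with an Ambion kit, and libraries followed the standard Illumina procedure. Groups were taken from the tissue label of each sample. The data analysed here are 1 table of the whole series in which the authors compared both groups gene by gene. It holds 35091 genes on 12 chromosomes, with 1 value per group and no column of a single sample.

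Per the file headers, the table gives a value for each group, a log2 fold change, a test statistic, a p-value, a q-value and a status word for each gene. The group values are read as FPKM made by the authors, because the column layout and status words are those of a Cuffdiff comparison table; the unit itself is not printed in the header. The aligner, the program version, the genome build and the annotation are not given in the sources used here, nor is how the 4 samples of a group entered its value. Positions are therefore printed as the deposited table gives them, with no build named. The deposited test statistic is a score with no fixed range, and it was used only to compare the size of the authors' error between kinds of genes. The deposited p-value has a smallest value of 5e-05, reached by 549 genes. The deposited q-value equals the Benjamini-Hochberg adjustment of the p-values over the tested genes within 5.2e-07.

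Of the genes, 19664 have the status OK and count as tested. A further 15381 have NOTEST (none above 4.98 FPKM), 44 have LOWDATA and 2 have HIDATA. The authors' log2 column holds spreadsheet error text in 1121 cells, all with a dormant value of 0, so log2 ratios of nondormant over dormant were recomputed from the deposited FPKM values, with no pseudocount. They equal the printed ratios, with the sign turned, within 0.0029. Genes with a value of 0 in 1 group have no ratio and are counted separately, since a listed 0 can be a failed estimate. The values sum to 844516 FPKM in nondormant and 852615 FPKM in dormant meristems. Read depth per sample is unknown, so precision from depth cannot be stated.

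Before the data were examined, a limma test on per-sample log2 values, tests of gene lists chosen by description, per-season ratios and enrichment of gene descriptions had been planned. None of these could be applied, because each needs per-sample values or gene descriptions. The authors' calls (deposited q of 0.05 or less) stand in their place as the main result, and whatever spread between samples they rest on cannot be examined here. Gene lists, including those for other tissues an excised bud can hold, gave no result: 0 of the table's identifiers matched the reference gene table of assembly SolTub_3.0, and the table holds no names. The rule for named genes was to take called genes at or above the median level of the tested genes, with the largest ratios in each direction. Its conditions on seasons and descriptions could not be applied, and it was limited to 2 genes per direction because identifiers have no names. Loci given by position alone were chosen after their values were seen.

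Shares have 95% exact (Clopper-Pearson) intervals, which cover counting error over genes only. Level classes are 10 equal groups of tested genes by the mean of both values. Chromosomes were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, as were bins of 1 Mb with at least 5 tested genes. Neighbouring tested genes were compared with 10000 shuffles of the calls within chromosomes, and the folds of both directions with as many shuffles of direction within level classes. Genes whose printed interval is identical to that of another gene (2470 genes on 1163 intervals) are treated here as overlapping gene models; how the authors' program assigned their reads is not given in the sources used here. Alternatives covered the threshold, the adjustment, filters on low values, pseudocounts of 0.1, 1 and 4, median scaling and quantile normalization. The tests were tested on simulated data with known answers. Shuffled calls gave a neighbour excess in 1 of 60 sets and planted pairs in 60 of 60, both counted for nondormant-higher pairs only. The shuffled sets follow the model of the test itself. They check its working and not other sources of an excess, such as shared reads. Fewer planted pairs were not tried. The 1 Mb scan called any bin in 1 of 20 shuffled sets and found a bin with 12 planted calls in 18 of 20. Smaller clusters were not planted, so how often the scan would find them is not known. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.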

Results

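Meristems are the bud tissues from which a potato tuber (Solanum tuberosum) sprouts, and after harvest they pass through dormancy, a period in which buds do not grow out. RNA sequencing was carried out on meristems excised from field-grown tubers of the cultivar Russet Burbank, in 8 samples. The 4 dormant samples were taken about 2 weeks after harvest in 4 different years, and the 4 nondormant samples came from tubers of the same harvests after storage at 4 °C until sprouts appeared. The design asks which transcripts differ in level between the dormant and the nondormant state. Time in storage and exposure to 4 °C differ between the groups together with dormancy. The share of other tissues in the excised buds may differ as well and could not be examined. The values analysed here are the authors' own comparison of the groups, with 1 expression value (read as FPKM) per gene and group, so no replicate error can be given for any level or fold, and read depth per sample is unknown. Calls are those of the authors, made at a deposited q of 0.05 or less, and ratios are nondormant over dormant throughout.

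The authors' deposited table called 2148 genes as different between nondormant and dormant meristems, 10.9% of the 19664 genes tested. Of these, 1410 were higher in nondormant and 738 higher in dormant meristems, so 65.6% of the calls were higher in nondormant (95% exact binomial interval 63.6% to 67.7%, which treats genes as independent). Over all tested genes, called or not, 47.2% were higher in nondormant meristems. The 1387 nondormant-higher genes with a value above 0 in both groups had a median fold of 4.05 (quartiles 2.96 and 6.01), and 711 of them (51.3%) differed at least 4-fold. The 735 such genes higher in dormant meristems had a median fold of 3.23 (quartiles 2.53 and 4.69), and 243 of them (33.1%) differed at least 4-fold. Part of this gap in fold goes with expression level, since low-level genes needed larger folds to be called and more of the nondormant-higher calls lay at low levels. The medians differed by 0.33 on the log2 scale, where shuffling directions within classes of like level gave 0.13 (two-sided permutation p = 0.0002, the smallest possible; chosen after seeing the data). Differences of at least 8-fold were found in 190 nondormant-higher and 42 dormant-higher genes. The dormant-higher genes had a median of 33.0 FPKM in dormant and 10.4 FPKM in nondormant meristems. For the nondormant-higher genes the medians were 17.2 FPKM in nondormant and 3.96 FPKM in dormant meristems. The dormant-higher genes had the higher median in dormant meristems and the lower one in nondormant meristems. Choosing the genes by direction favours this order.

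A further 23 genes called higher in nondormant meristems were listed at 0 in dormant meristems, with 0.821 to 10.2 FPKM in nondormant ones. Only 3 genes called higher in dormant meristems were listed at 0 in nondormant meristems, with 1.21 to 9.95 FPKM in dormant ones. No fold is given for these genes. The smallest fold called was 2.06 in either direction. A large ratio was not sufficient for a call, since 212 of the 444 tested genes that differed at least 8-fold were not called. Their median level was 1.09 FPKM, against 5.30 FPKM for the 232 that were called, and 174 of them were higher in nondormant meristems.

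**Figure D1:**
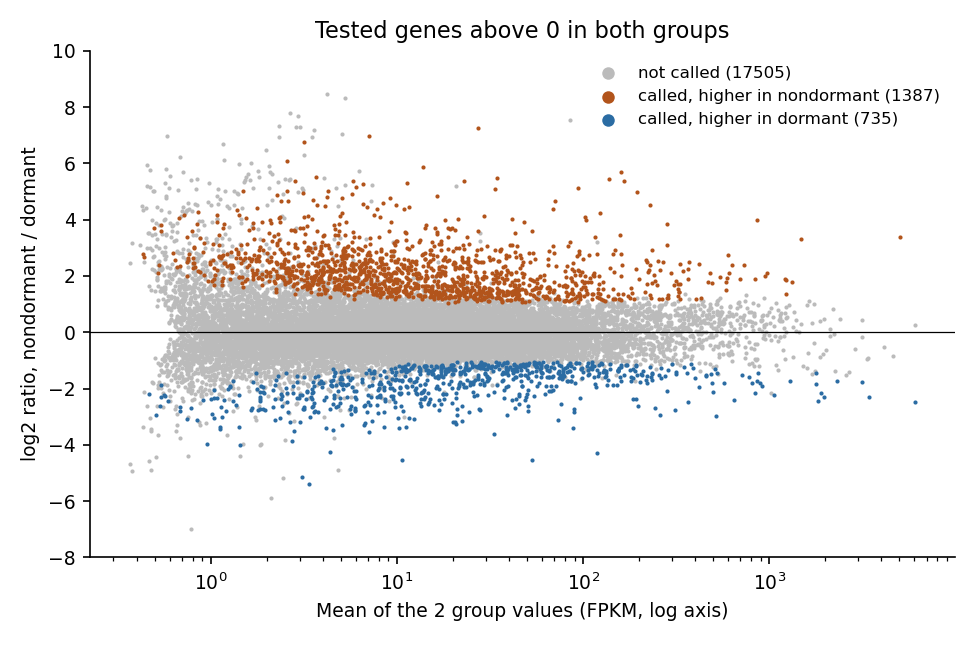
Log2 ratio of nondormant to dormant value (vertical axis) against the mean of both group values in FPKM (horizontal log axis) for the tested genes above 0 in both groups, each point being 1 gene. The 1387 genes called higher in nondormant meristems (orange) lie above 0 and the 735 called higher in dormant meristems (blue) below it, and 6 uncalled genes lie outside the plotted range of -8 to 10.

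The genes with the largest called ratios at or above the median level of the tested genes (11.6 FPKM) were all single loci known here by identifier and position, because the table pairs its identifiers with no gene names. PGSC0003DMG400002857, on chromosome 4 from 250809 to 253005, stood at 54.1 FPKM in nondormant and 0.354 FPKM in dormant meristems in the authors' deposited table, a 153-fold difference (log2 ratio 7.26, deposited q = 0.0210). The next tested gene on that chromosome, from 257058 to 257382, had values of 170 and 0.919 FPKM in the authors' deposited table and was not called (185-fold, deposited q = 0.0616). PGSC0003DMG400044996, on chromosome 1 from 51097741 to 51098212, had 27.1 FPKM in nondormant and 0.465 FPKM in dormant meristems in the authors' deposited table (58.3-fold, log2 ratio 5.86, deposited q = 0.0487). In the other direction, PGSC0003DMG400001598, on chromosome 1 from 80055735 to 80056866, had 102 FPKM in dormant and 4.39 FPKM in nondormant meristems in the authors' deposited table (23.4-fold, log2 ratio -4.55, deposited q = 0.00179). PGSC0003DMG400009255, on chromosome 11 from 12252235 to 12253052, had 227 FPKM in dormant and 11.5 FPKM in nondormant meristems in the authors' deposited table (19.7-fold, log2 ratio -4.30, deposited q = 0.00179). Both nondormant-higher genes lose their call at a q under 0.01, and their folds rest on dormant values under 1 FPKM. With a pseudocount of 1 their log2 ratios are 5.35 and 4.26, and after quantile normalization of the log2 values with that pseudocount they are 5.24 and 4.16.

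Some of the most abundant transcripts of the tissue were among the called genes. In the authors' deposited table, the 20 genes with the highest dormant values held 9.95% of the summed dormant FPKM, and 9 of them were called, all 9 higher in dormant meristems. The 20 genes with the highest nondormant values held 7.33% of the summed nondormant FPKM, and 3 of them were called, all 3 higher in nondormant meristems. These lists had 8 genes in common. Each was ranked by the value of 1 group, which favours genes higher in that group, so the direction of these calls follows in part from the ranking. The highest dormant value in the authors' deposited table belonged to a locus on chromosome 3 from 20807645 to 20808427, with 10283 FPKM in dormant and 1835 FPKM in nondormant meristems (5.61-fold, deposited q = 0.00179). By itself it made up 1.21% of the summed dormant values. The highest nondormant value in the authors' deposited table belonged to a locus on chromosome 7 from 39619065 to 39620684, with 9202 FPKM in nondormant and 878 FPKM in dormant meristems (10.5-fold, deposited q = 0.0353). On chromosome 5, the locus from 44728116 to 44729737 had 2674 FPKM in nondormant and 267 FPKM in dormant meristems in the authors' deposited table (deposited q = 0.00179). On chromosome 6, the locus from 1845820 to 1850085 had 2051 and 603 FPKM in the authors' deposited table (3.40-fold, deposited q = 0.00747).

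Of the 9 abundant genes called higher in dormant meristems, 5 lay on chromosome 3, and 4 of these lay within 441 kb, from 20367569 to 20808427. The authors' deposited table tested 16 genes in this stretch, which was singled out after its values were seen. It called 5 of them, all higher in dormant meristems by 3.58-fold to 5.61-fold, and the 11 uncalled genes also had higher dormant than nondormant values. Together the 16 genes held 2.90% of the summed dormant and 0.628% of the summed nondormant FPKM. The ends of the stretch were set by the 4 abundant dormant-higher genes, so their calls and much of these shares follow from that choice. In a scan of 1 Mb bins, the bin from 20 to 21 Mb held 7 dormant-higher calls among 44 tested genes, with 1.65 expected. It did not pass (two-sided Fisher's exact test, adjusted p = 0.249). The stretch also holds 2 genes with the status HIDATA, which were not tested and are listed at no more than 1.74 FPKM. Listed values under this status are not read as levels, so the shares and the ranking by value say nothing of these 2 genes.

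The direction of calls varied with expression level. With the tested genes divided into 10 classes of equal size by mean FPKM, 72.0% of the called genes of the lowest class were higher in nondormant meristems and 54.3% of those of the highest class. The fall was not steady: counted from the lowest, class 2 had the highest share (78.9%) and class 9 the lowest (51.4%). Below the median level, 738 called genes were higher in nondormant and 258 higher in dormant meristems (74.1%, exact interval 71.3% to 76.8%). Above it, the numbers were 672 and 480 (58.3%, exact interval 55.4% to 61.2%), and the shares differed by Fisher's exact test (odds ratio 2.04, two-sided p = 1.6e-14). That test treats genes as independent. In the 2 highest classes together, 303 genes were higher in nondormant and 268 in dormant meristems (53.1%, exact interval 48.9% to 57.2%, which includes an equal split). The share of tested genes that was called ran from 6.71% in the lowest to 16.5% in the highest class, and the smallest called fold was 3.17 in the lowest and 2.06 overall. For the trend in direction, fewer reads behind the dormant values and a difference between the states cannot be told apart.

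**Figure D2:**
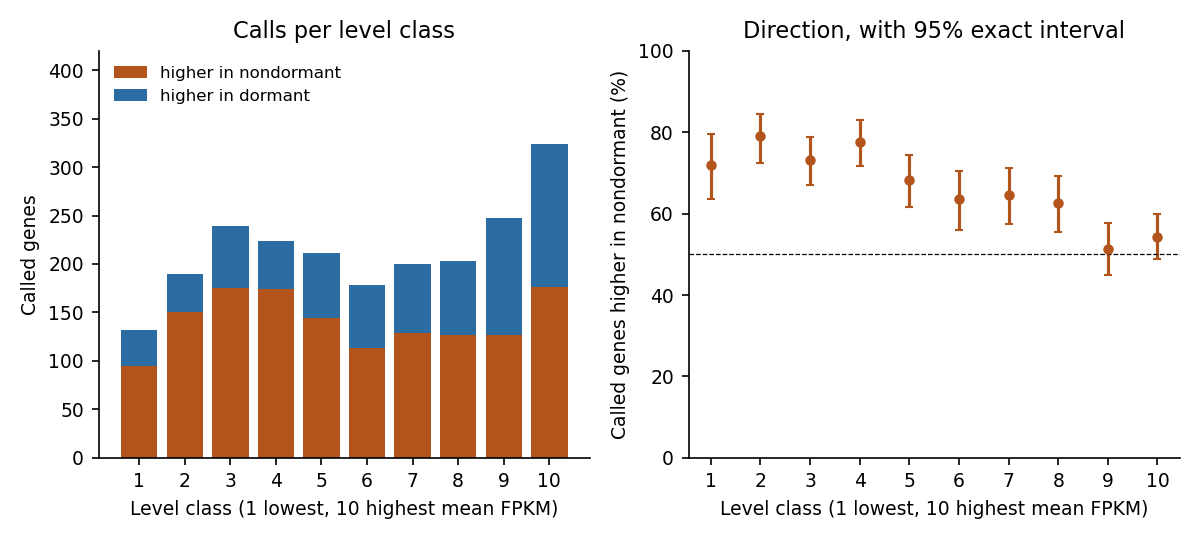
Called genes per class of mean FPKM (left, number of genes higher in nondormant in orange and higher in dormant in blue, stacked) and the share of called genes higher in nondormant meristems (right, percent, with 95% exact binomial intervals as bars and an equal split as the dashed line). The share is 72.0% in the lowest and 54.3% in the highest class.

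Called genes were spread over all 12 chromosomes. The called share of tested genes ran from 9.96% on chromosome 8 to 12.1% on chromosome 12, and no chromosome differed from the rest by Fisher's exact test in the called share (lowest adjusted p = 0.723 over 12 chromosomes) or in the direction of its calls (lowest adjusted p = 0.509). An unadjusted p under 0.05 was reached by 0 chromosomes in either test. In 515 bins of 1 Mb tested for each direction, 0 bins held more or fewer called genes than the rest at an adjusted p under 0.05 (two-sided Fisher's exact test, lowest adjusted p = 0.0548). This scan was chosen after the chromosome 3 stretch had been seen. With calls restricted to a q under 0.01, 2 bins passed, on chromosome 1 from 1 to 2 Mb for nondormant-higher genes (12 of 54 tested, 1.94 expected, adjusted p = 0.000364) and on chromosome 4 from 6 to 7 Mb for dormant-higher genes (7 of 58 tested, 0.903 expected, adjusted p = 0.0162).

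At the scale of single genes, called genes lay next to called genes of the same direction more often than shuffled calls did. Among neighbouring tested genes, 144 pairs were both higher in nondormant meristems, against a mean of 101 in 10000 shuffles of the calls within chromosomes (1.43 times, two-sided permutation p = 0.0002, the smallest these shuffles can give). In 64 pairs both genes were higher in dormant meristems, against 27.7 in the shuffles (2.31 times, permutation p = 0.0002). Pairs of opposite direction numbered 85, fewer than the shuffled mean of 106 (permutation p = 0.0342), but at a q under 0.01 they numbered 19 against 21.8 (permutation p = 0.633), so this deficit did not hold there. In all, 381 called genes belonged to a same-direction pair.

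**Figure D3:**
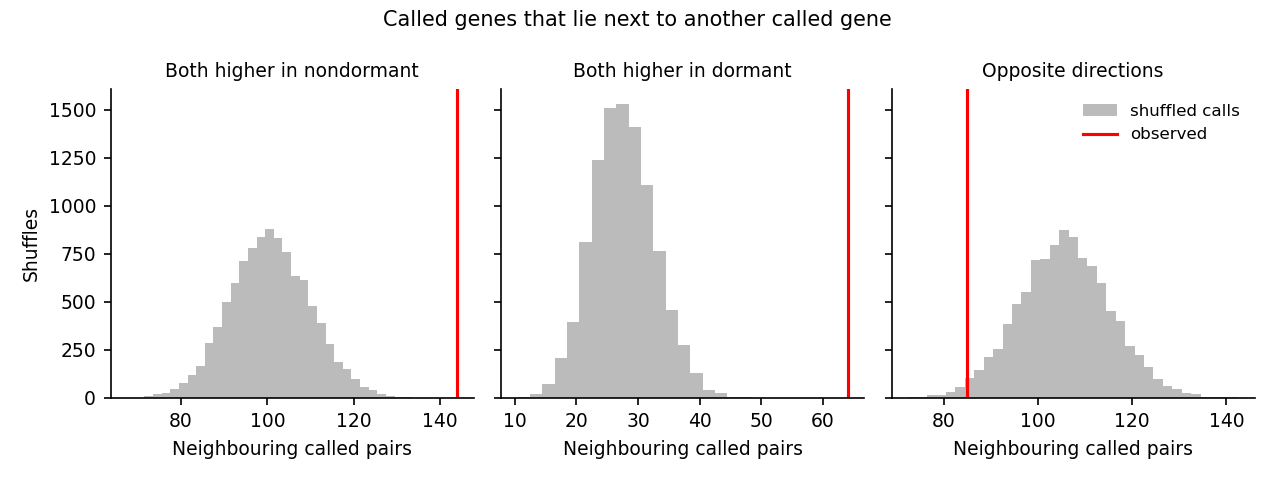
Number of neighbouring pairs of called genes in 10000 shuffles of the calls within chromosomes (grey, number of shuffles on the vertical axis) and in the table (red line), for pairs both higher in nondormant, both higher in dormant, and opposite. The observed 144 and 64 same-direction pairs lie above the shuffled means of 101 and 27.7, and the 85 opposite pairs lie below the mean of 106.

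Runs of at least 4 consecutive tested genes called in the same direction occurred 5 times, against a shuffled mean of 0.50 and a highest shuffled count of 6 (one-sided permutation p = 0.0005). On chromosome 1 from 1636073 to 1849616, 5 genes were higher in nondormant meristems by 4.44-fold to 8.30-fold in the authors' deposited table. On chromosome 6 from 47744174 to 47775076, 5 genes within 30.9 kb were higher in nondormant meristems by 4.62-fold to 10.5-fold. On chromosome 10, 5 genes within 27.7 kb, from 46614488 to 46642148, were higher in nondormant meristems by at least 4.34-fold. A run of 4 genes on chromosome 6 from 51908938 to 51973807 was higher in nondormant meristems by 2.26-fold to 3.07-fold. Runs skip untested genes: 16 genes of the table lie in the span of this run, and 6 to 9 in each of the other 4. The single run of dormant-higher genes lay on chromosome 3 from 16174064 to 16332897, where 5 genes differed by 3.31-fold to 5.61-fold and reached 3268 FPKM in dormant against 656 FPKM in nondormant meristems in the authors' deposited table.

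**Figure D4:**
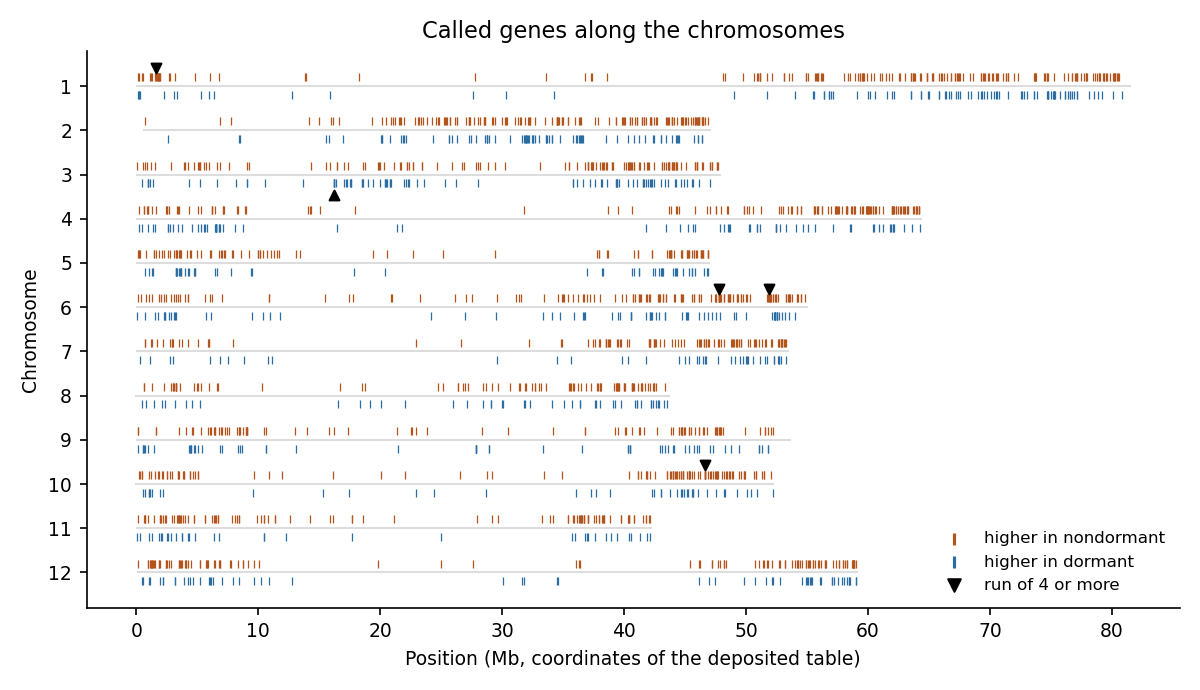
Positions of the called genes along the 12 chromosomes (Mb, coordinates of the deposited table), with genes higher in nondormant meristems as orange ticks above each line and genes higher in dormant meristems as blue ticks below it. Black triangles mark the 5 runs of at least 4 consecutive tested genes with the same direction, 4 of them higher in nondormant and 1 higher in dormant meristems.

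Most genes that reached 1 FPKM in 1 state also reached it in the other. A value of at least 1 FPKM was listed for 18556 genes in nondormant and 18262 genes in dormant meristems, 17524 of them in both. Across 19627 tested genes above 0 in both groups, the log2 values correlated with a Pearson r of 0.886 and a Spearman rho of 0.913, where genes are not independent replicates. The median log2 ratio of these genes was -0.05. More genes were listed at 0 in dormant meristems alone (1123) than in nondormant meristems alone (608).

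Genes that shared their printed interval with another gene were called less often. Of 1815 such genes tested, 68 were called (3.75%, exact interval 2.92% to 4.73%), against 2080 of 17849 genes with an interval of their own (11.7%, exact interval 11.2% to 12.1%; Fisher's exact test, p = 6.0e-31). The median absolute log2 ratio was 0.47 in the former and 0.52 in the latter. The intervals and the test treat genes as independent, although genes of the same interval may share reads.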

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

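All tests in this part were chosen after the patterns they bear on had been seen; for neighbours, the bounds on expression level and on shared reads were written before those tests were run.

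Among the 2 genes with the status HIDATA and the 44 with LOWDATA in the authors' deposited table, 6 had at least 1 FPKM in 1 group and either a difference of at least 8-fold or a 0 in the other. Genes with the status NOTEST were not screened in this way. Both loci with the status HIDATA lie on chromosome 3 within the stretch of abundant dormant-higher genes. In the authors' deposited table the locus from 20611551 to 20612220 is listed at 1.74 FPKM in nondormant and 0 in dormant meristems. The authors' deposited table lists the locus from 20707647 to 20708500 at 1.27 FPKM and 0. A 0 under this status is not read as absence of the transcript. The other 4 loci have the status LOWDATA and share their interval with another gene, as do all 44 genes of that status. On chromosome 5 from 43807587 to 43809214 the authors' deposited table has 31.4 FPKM in nondormant and 2.15 in dormant meristems, and a called gene on the same interval has 97.9 and 8.11 FPKM (deposited q = 0.00179). On chromosome 12 from 58818942 to 58820484 the values in the authors' deposited table are 32.2 and 2.96 FPKM. On chromosome 10 from 50692665 to 50700798 they are 3.99 and 0.00686 FPKM in the authors' deposited table. On chromosome 6 from 47903950 to 47910482 the authors' deposited table lists 0 in nondormant and 1.09 FPKM in dormant meristems.

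More called genes were higher in nondormant than in dormant meristems, and more genes were listed at 0 in dormant meristems alone. A single scaling offset for all genes is argued against. The median log2 ratio was -0.05, and 63.4% (exact interval 62.0% to 64.8%) of the genes at least 2-fold apart after centring on it were higher in nondormant meristems. These genes include called ones, so the share is not independent of the pattern, and its interval treats genes as independent. Fewer reads behind the dormant values may account for the zeros: in short untested loci, the fifth percentile of non-zero values times locus span was 1.34 times higher in dormant meristems (bootstrap interval 1.26 to 1.40). For the direction of the calls, fewer reads and a difference between the states cannot be told apart at any level: the share higher in nondormant was 58.3% (55.4% to 61.2%) above the median level but 53.1% (48.9% to 57.2%) in the 2 highest classes, where an equal split is included, and the share that a ratio of 1.34 would give is not known. The dormancy state, storage time, cold and the share of other tissues in the excised buds stay open as untested sources.

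Called genes lay next to called genes of the same direction. Overlapping gene models are argued against, since without genes of shared intervals there were 205 same-direction pairs (shuffled mean 132, permutation p = 0.0002, the smallest possible), and like expression levels of neighbours by 208 pairs against 129 when calls were shuffled within level classes (permutation p = 0.0002). For reads shared between adjacent gene copies, log2 ratios within pairs differed by a median of 0.547 (0.450 to 0.647), above the bound of 0.1 set in advance for a fixed ratio. This argues only against complete sharing of reads in most pairs. A further bound set in advance, a difference above that of same-direction genes drawn at random (0.635, 0.528 to 0.752), was not met. Separately regulated genes would differ about as much as random ones, so that comparison cannot decide. Shared reads as a cause of the excess therefore stay open. Reads shared in part or in single pairs, and shared regulation of neighbours, were not tested.

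Genes of shared intervals were called less often. Within level classes the odds ratio of a call was 0.317 (0.248 to 0.406), which argues against lower levels as the whole cause. Among genes 2-fold to 8-fold apart, 60 of 336 were called against 1830 of 3834 (odds ratio within level and fold classes 0.202, 0.136 to 0.302), which argues against smaller differences. Whether a larger error from shared reads lies behind the rest stays open. The authors' test statistic per unit of log2 ratio was 0.691 times that of other genes of like level (bootstrap interval 0.660 to 0.721). The statistic and the calls come from the same comparison, so this is not independent of the lower call rate. How the calls were made from it is not given. The intervals of the odds ratios treat genes as independent, including those of the same interval. No biological explanation was tested.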

How the results depend on the processing

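The q threshold and the adjustment moved the counts most. At a q under 0.01 there were 1011 called genes, 705 higher in nondormant and 306 in dormant meristems, and under Benjamini-Yekutieli adjustment 722, 528 and 194; both rules are stricter by construction. Other filters and a minimum log2 ratio of 1 gave 1619 to 2153 calls. Same-direction neighbours outnumbered shuffled calls under all 4 alternatives run for them, whereas the deficit of opposite pairs was lost at a q under 0.01 (permutation p = 0.633). Pseudocounts and scalings leave the deposited q as it is and could not turn the direction of the named genes, so they test no call, but a pseudocount of 4 lowered the largest log2 ratio from 7.26 to 3.74. The scan of 1 Mb bins found 0 bins as called or with bins moved by 0.5 Mb, and 2 at a q under 0.01, and the cause was not tested. Benjamini-Yekutieli adjustment, a mean of at least 1 FPKM, leaving out shared intervals, the shuffling of directions within level classes, and the alternatives for neighbours and bins were chosen after seeing the data. No paired analysis was possible because the table holds 1 value per group, although the samples pair by harvest. For that reason leaving out samples, other splits of the samples, the season block and other test programs were not run. Leaving out storage protein genes and all alternatives for gene lists were not run because the identifiers matched no names. Depth is unknown, which limits what can be said of low values.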

Other observations

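The tests of gene density and locus span were chosen after the calls had been examined, with their bounds written before they were run.

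Called genes lay in slightly more gene-dense chromosome parts. They had 83.3 other genes of the table within 500 kb, against 81.1 for uncalled genes, a difference of 2.12 genes where shuffling within chromosome and level class gave 0.339 (permutation p = 0.0070). The shuffles move single genes, whereas neighbours share most of a window and called genes lay next to each other, so this p may overstate the evidence. The difference is small beside the number of genes in such a window, and its source was not tested.

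Called genes outside shared intervals also spanned shorter loci. Their median span was 2.65 kb against 3.36 kb for uncalled genes, a difference of -0.709 kb (permutation p = 0.0002 within level classes, the smallest possible). The medians were 2.74 kb for genes higher in nondormant and 2.44 kb for genes higher in dormant meristems. Span includes introns, so transcript length was not measured.

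The uncalled gene with the highest level among those at least 8-fold apart is 1 of 3 genes that share an interval on chromosome 2, from 43665896 to 43674945. It had 214 FPKM in nondormant and 23.2 FPKM in dormant meristems in the authors' deposited table (9.23-fold, deposited q = 0.108). Another gene of that interval was called in the authors' deposited table, with 438 and 19.3 FPKM (22.7-fold, deposited q = 0.0303). Of the 212 such uncalled genes, 7 had a mean of at least 10 FPKM.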
